A study of Mus musculus with 13 samples.

How the data were processed

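RNA of whole brain was measured by sequencing in 13 mice of 4 Adar genotypes (wild type, n = 3; P195A/+, n = 3; P195A/P195A, n = 4; P195A/-, n = 3). The libraries are strand-specific per the options in the file headers. Genotype, replicate number, sex, age and weaning weight came from the labels. For P195A/- the short genotype label was used; the longer label of the same animals writes the P195A allele on both sides and adds AdarKO/+, which the labels do not explain.

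The authors deposited a table of estimated counts per gene (expected counts), which per the submitters' processing notes came from reads trimmed with fastp 0.19.5 and quantified with Salmon, with edgeR named as a further tool; versions of Salmon and edgeR, the index, the annotation and any summing of transcripts are not given in the sources used here. Of its nonzero values, 99.5% are not whole numbers and library totals range from 13539148 to 22399005, so they had not been scaled to a common total; whether transcript lengths entered them was not tested. Of 54307 entries, 51482 were matched by gene ID to GENCODE M21 (GRCm38), and the others held 0.68% of the counts; the versioned ID was identical in 35, so a different annotation release had been used and coordinates are those of M21. The authors also deposited read counts of A, C, G and T at sites from a list of editing sites, from JACUSA2 2.0.0-RC5 on mm10, as tables per library and per comparison of 2 genotypes. Per the file headers, reads marked as duplicates were left out, the minimum coverage was 3 and the depth of the comparison tables was capped at 3000. The deposited score of each site in the comparison tables is the JACUSA2 statistic for a difference between genotypes. The aligner is not given in the sources used here.

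The estimated counts were rounded and fitted with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, robust, TMM scaling, filterByExpr), all 13 libraries in 1 fit with a coefficient per genotype, leaving 19962 genes and a biological coefficient of variation of 19.1%. The contrasts were P195A/+, P195A/P195A and P195A/- against wild type, and P195A/- against P195A/P195A, as in the deposited comparison tables. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Expression is given as CPM after TMM scaling. For genes at or near 0, ratios of counts with 95% exact intervals are given in place of fitted fold changes, against a floor of 3 counts over the group where a group had 0; such intervals and floors cover counting error only. Sets of genes were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over 24 lists written from textbook knowledge, of whose 515 symbols 458 were measured; some symbols stand in more than 1 list. An added list of 16 olfactory bulb markers, 15 measured, was written after the data were examined and is not part of the adjustment. Parent genes of near-identical copies were found with BLAST 2.17.0, and features located with bedtools 2.31.1.

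Editing was tested on sites with a reference A on the transcript strand, at least 10 A plus G reads in each library of the comparison and a pooled level of 1 to 99%. Library tables list a site only where a non-reference read was seen, so the comparison tables were used, each in a fit of its own; the fit was edgeR's quasi-likelihood test with an edited and an unedited column per library and a log2 odds ratio as effect. That test shares its estimate of spread partly over sites, so at deep sites its p can understate the spread between animals. Median depth was 22 to 25 reads per library and site, which limits single-site precision. Mean editing per library is the unweighted mean level over the tested sites, compared by exact two-sided permutation (the smaller tail doubled; a first coding by absolute difference, which gave a smaller p for P195A/P195A, was replaced) and over the 4 genotypes by a permutation F test. Weaning weights were compared by exact two-sided permutation in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9). The correlation used 100000 resamples, and all 5184 orders within genotypes.

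Tests, comparisons, lists, naming rules and most alternatives were set before the data were examined. Named genes are Adar, Adarb1 and Adarb2; per comparison up to 10 passing genes of at least 1 CPM with the largest rise and up to 10 with the largest fall; the 5 smallest p where fewer than 5 passed; 3 members with the smallest p of each passing list and of the interferon, stress response and MHC class I lists; and sex-linked controls. Named sites are, per comparison, the 5 passing sites with the smallest p and, in up to 10 genes with known recoding sites, the coding site with the most reads. The interval from Adar to Tpm3, the group of genes present in some genotypes and near 0 in others, and the olfactory list were chosen after seeing values; a first definition of the interval with protein-coding genes only held fewer of the passing genes.

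Alternatives were other scaling, no filter or a filter at 1 CPM, DESeq2 1.42.0, limma-voom, sex or replicate number as a covariate, fits of only 2 genotypes, animals of 1 age, other read minimums and level limits, limma on log2 ratios with an offset of 0.5, Fisher's exact test on pooled reads, camera with an estimated correlation, fry, pooled reads for the mean level, and leaving out each library in turn. Counts of calls over all other splits of the libraries of a comparison were made as well. Sites outside ribosomal repeats (chromosome 17, 39843013 to 39848827), a fit of all 13 libraries, sites read in all 13, the omission of P195A/P195A replicates 2 and 3 and weaning weight at 1 age and weaning age were added after seeing the data. Libraries of a genotype were checked for being copies of each other by a chi-square of their counts over genes with at least 20 counts; over 15 pairs it was 7.19 to 43.2 per degree of freedom, above the 1 of repeated sampling.

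The pipeline was tested on simulated data with 200 changed genes per comparison. At a 2-fold change it recovered 70%, 62%, 80% and 46% in the order of the contrasts above, at 1.5-fold 12%, 42%, 26% and 18%, at 4-fold 88%, 90%, 96% and 98%, and at 8-fold 98%, 98%, 98% and 94%, with 8, 8, 7 and 6 false calls. For editing, a shift of 20 points at sites of under 50 reads was recovered in 4%, 4%, 0% and 4%, and 35 points in 38%, 70%, 36% and 76%; at 50 or more reads 20 points were recovered in 9.52%, 16.7%, 5.88% and 13.2% and 35 points in 95.1%, 91.2%, 87.9% and 97.4%, with 2, 1, 1 and 4 false calls. These shifts replaced a first design of 10 and 20 points, which recovered almost none. They were simulated only at sites with a pooled level near the middle of the range. The spread between libraries was an assumed one, with an intraclass correlation of 0.01. Recovery at sites of low or high level was not tested.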

Results

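RNA of the whole brain was sequenced from 13 mice of the C57BL/6 strain in 4 genotypes of Adar, the gene of the enzyme ADAR1, which converts adenosine to inosine in double-stranded RNA. P195A is a substitution in the Z-nucleic acid binding domain of the long form of ADAR1, and the mouse counterpart of a human disease variant. There were 3 wild-type animals, 3 with a P195A allele and a wild-type allele (P195A/+), 4 with P195A on both alleles (P195A/P195A) and 3 with P195A opposite a null allele (P195A/-). Library totals ranged from 17891377 to 22399005 gene counts in wild type, 18540118 to 21272435 in P195A/+, 13539148 to 20688387 in P195A/P195A and 15591470 to 18359307 in P195A/-. Wild-type animals were 48, 48 and 74 days old, P195A/+ animals 43 days, P195A/P195A animals 42 or 48 days and P195A/- animals 42 days. The level of Xist and of Ddx3y matched the sex given for every animal. Mitochondrial genes took 1.57% of the counts in P195A/- replicate 3 and 0.46 to 0.79% in each other library. The first principal component held 20.4% of the variance of all tested genes and was set at its ends by P195A/P195A replicate 2 (53.5) and replicate 3 (-49.1).

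Mice with no wild-type Adar allele were lighter at weaning. Their weight was 7.80 g ± 0.72 (SD, n = 7), against 9.97 g ± 0.76 (n = 6) in mice with 1 or 2 wild-type alleles, a difference of -2.17 g (exact two-sided permutation p = 0.00117, the smallest this design allows). The ranges were 6.4 to 8.4 g and 9.0 to 10.7 g. Among females the difference was -2.14 g (exact permutation p = 0.0159, again the smallest possible). P195A/P195A animals differed from wild type by -2.41 g and P195A/- animals by -1.77 g, with exact permutation p of 0.0571 and 0.1, the smallest that groups of these sizes allow, and 0.2 for both after adjustment over the 4 genotype comparisons. The difference between P195A/+ and wild type was 0.07 g and that between P195A/- and P195A/P195A was 0.64 g, with exact permutation p of 1 and 0.4 (adjusted 1 and 0.533). Weaning age differed with this grouping, at 19 to 20 days in mice with no wild-type allele, 19, 19 and 24 days in wild type and 21 days in P195A/+. These permutations exchange mice of different age and weaning age and so take no account of either. Only mice of 48 days weaned at 19 days were present in both groups, at 9.0 and 10.5 g in wild type and 7.3 and 8.0 g in P195A/P195A (-2.1 g; exact permutation p = 0.333, the smallest possible), an alternative chosen after the data were seen.

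Adar RNA (ENSMUSG00000027951; chromosome 3, 89715022 to 89753446 in GRCm38) was lowest in wild type, at 180 CPM (gene counts scaled to library size) ± 13.3 (SD, n = 3). It stood at 239.8 ± 6.63 CPM in P195A/+ (n = 3), 323 ± 28.6 in P195A/P195A (n = 4) and 201 ± 4.28 in P195A/- (n = 3). By library the values were 186.7, 164.8 and 188.8 in wild type, 242.3, 244.9 and 232.3 in P195A/+, 345.6, 282.4, 340.3 and 322.5 in P195A/P195A, and 196.3, 203.8 and 203.7 in P195A/-. Adarb1, which encodes the related editing enzyme ADAR2, had 305.5 ± 19.9, 316 ± 35.6, 303.8 ± 25.3 and 304.9 ± 7.21 CPM in the same order. Adarb2, whose product has no known editing activity, had 43.9 ± 3.18, 42.1 ± 0.991, 58.4 ± 12.2 and 49.5 ± 6.98 CPM.

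**Figure D1:**
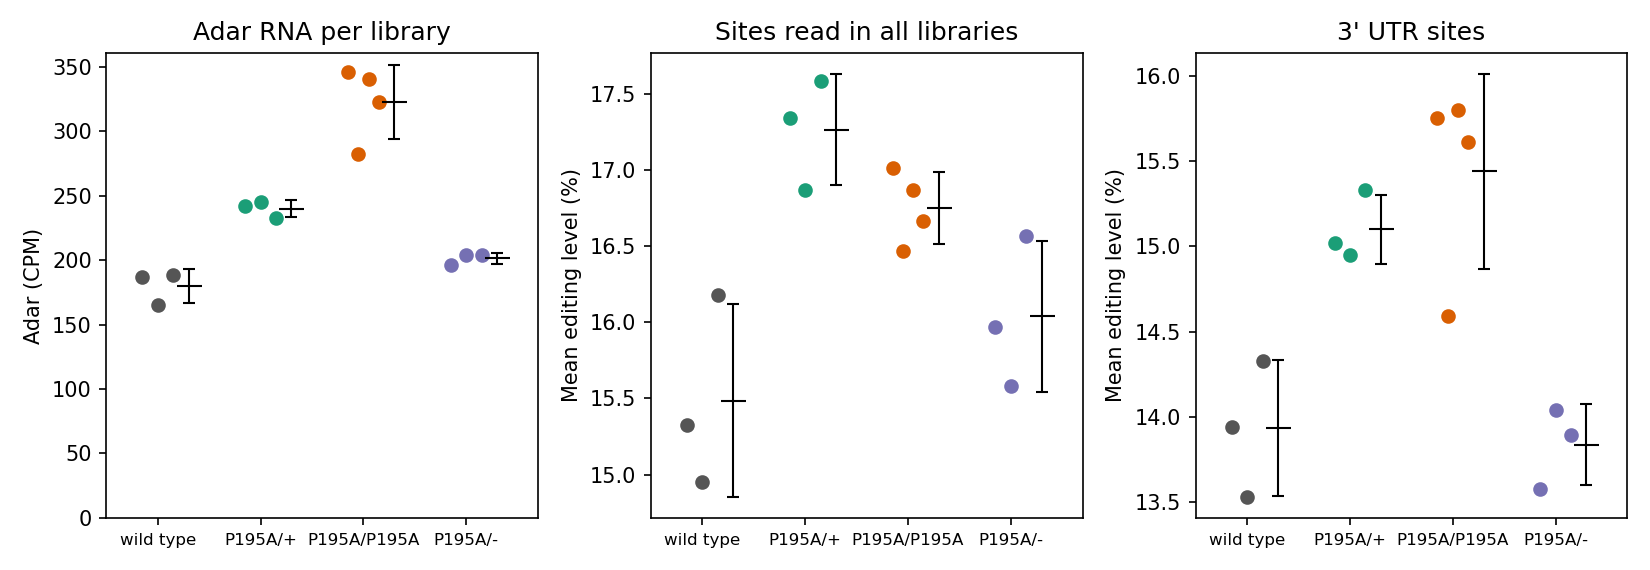
Adar RNA in CPM (left), mean editing level in percent over 9791 sites read in all 13 libraries (middle) and over the 1858 of them in 3' UTRs (right), with a point per library, and the mean and SD of each genotype in black. Adar stood at 180 CPM in wild type and 323 CPM in P195A/P195A, and mean 3' UTR editing at 13.9% and 15.4%; the editing axes do not start at 0.

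The first comparison, P195A/+ against wild type, addresses what a single P195A allele does beside a wild-type allele. Atp8b2, a phospholipid flippase gene near Adar (chromosome 3, 89939481 to 89963508), rose from 115.7 ± 7.13 CPM (SD, n = 3) to 187 ± 7.06 (n = 3), a log2 fold change of 0.69 (SE 0.0811; adjusted p = 0.00236). Other genes next to Adar had similar values without passing: Ube2q1, a ubiquitin-conjugating enzyme gene, 0.73 (adjusted p = 0.211), 4933434E20Rik 0.70 (0.211), Ubap2l 0.56 (0.206) and Adar itself 0.41 (0.232). DESeq2 called these 4, with adjusted p of 0.00124, 0.00144, 0.00124 and 0.00437 in that order. Gm3608, a gene on chromosome 1 (105455971 to 105458829) that is 99.55% identical to Capza1, fell from 29.7 to 0.321 CPM, 88.3-fold lower (95% counting interval 57 to 145; adjusted p = 3.86e-04); its reads cannot be told from those of Capza1 with certainty. In all, 1 gene rose and 1 fell among 19962 tested; 895 had an unadjusted p under 0.05, where chance gives 998. DESeq2 passed 19 genes, a fit of only these 2 genotypes 11, the set without a filter on low counts 7 and limma-voom 2. Without wild-type replicate 2 the count was 1, and Atp8b2 no longer passed (log2 fold change 0.65, adjusted p = 0.0534).

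Interferon-stimulated genes, the antiviral genes switched on by interferon, were lower in P195A/+ as a set, with a median log2 fold change of -0.21 over 51 measured genes, 39 of them lower (limma's camera, adjusted p = 4.00e-04). This call was lost with an estimated correlation (adjusted p = 0.53 with an estimated correlation). By edgeR no member passed over all genes or adjusted over the list alone, and 7 had an unadjusted p under 0.05, all lower; Oasl2 had -1.04, Ddx60 -0.98 and Rsad2 -0.94. Targets of the glucocorticoid receptor were lower in 16 of 16 (median -0.26, adjusted p = 3.07e-05; adjusted p = 0.53 with an estimated correlation), with Sgk1 at -0.56 and Fkbp5 at -0.39. Immediate early genes of neuronal activity were lower, at a median of -0.16 (adjusted p = 0.0288; adjusted p = 0.931 with an estimated correlation), with Fosb at -0.80; 1 member passed adjusted over the list alone. Myelin genes of oligodendrocytes were higher by camera, with a median of 0.23 over 15 genes (adjusted p = 4.00e-04, and adjusted p = 0.595 with an estimated correlation). Opalin had 0.65 and Cldn11 0.40. By edgeR 3 passed adjusted over the list alone and none over all genes, while DESeq2 passed Opalin over all genes (adjusted p = 0.0225). Precursors and newly formed oligodendrocytes (median 0.13, adjusted p = 0.0311) and endothelial cells and pericytes (0.12, 0.0288) were higher too, with adjusted p = 0.53 and adjusted p = 0.931 with an estimated correlation. In total 3 lists were higher and 3 lower of 24, and 0 passed with an estimated correlation or with fry. Without P195A/+ replicate 3 there were 3 lists, and the calls of oligodendrocytes (0.13), their precursors (0.04), endothelial cells (0.02) and immediate early genes (-0.10) were lost. Without wild-type replicate 1 there were also 3, with precursors at 0.14, endothelial cells at 0.12 and immediate early genes at -0.12. The precursor call was lost without wild-type replicate 3 (0.08), and the immediate early call without wild-type replicate 2 (-0.04) or P195A/+ replicate 2 (-0.13). Markers of the olfactory bulb, a list added after the data were examined, were lower beside these, in 14 of 15 genes (median -0.45).

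In P195A/P195A against wild type, which addresses the effect of the mutation without a wild-type allele, the genes that rose were Adar and its neighbours. Adar rose 0.84 on the log2 scale (SE 0.0775; adjusted p = 5.91e-05), Atp8b2 0.99 (SE 0.0774; 1.62e-05), Ubap2l 0.98 (SE 0.0927; 6.36e-05), Ube2q1 1.00 (SE 0.125; 0.00216), Tpm3, a tropomyosin gene, 0.97 (SE 0.134; 0.00614) and 4632404H12Rik 0.84 (SE 0.111; 0.00367). Smaller margins were met by 4933434E20Rik at 0.77 (adjusted p = 0.0244), Il6ra, which encodes the interleukin 6 receptor, at 1.01 (0.0495) and Chrnb2, a nicotinic acetylcholine receptor subunit gene, at 0.71 (0.0495). Chrnb2 (89746195 to 89764632) overlaps the end of Adar in position. Whether reads of the overlap affect its value was not tested, and the libraries are strand-specific. Gm3608 fell to 0.312 CPM, 90.2-fold lower (counting interval 59.4 to 144; adjusted p = 5.60e-05), with the same limit on shared reads. In all, 9 genes rose and 1 fell, with 1176 at an unadjusted p under 0.05; DESeq2 passed 19, limma-voom 7, a fit of only these genotypes 5 and animals of 48 days alone 5.

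Leaving out a library changed part of these calls, while Adar, Atp8b2, Ubap2l, Ube2q1 and Gm3608 passed in each of the 7 fits. Over all 18 alternatives, Ubap2l and Ube2q1 passed in 17 each, with an adjusted p of up to 0.114 and 0.0648. Without wild-type replicate 1 the count was 5, and Il6ra (1.02), Tpm3 (0.90), 4632404H12Rik (0.81), 4933434E20Rik (0.74) and Chrnb2 (0.71) did not pass. Without wild-type replicate 3 it was 6, and Il6ra (1.01), Tpm3 (0.99), 4933434E20Rik (0.77) and Chrnb2 (0.72) did not pass. Il6ra and Chrnb2 also failed without wild-type replicate 2 (1.00 and 0.71) and without P195A/P195A replicate 1 (1.02 and 0.69), replicate 3 (0.90 and 0.62) or replicate 4 (0.96 and 0.70). The call of 4933434E20Rik was lost without wild-type replicate 2 (0.80) and without P195A/P195A replicate 1 or 4 (0.77 each). Genes at an unadjusted p under 0.05 numbered from 726 without wild-type replicate 3 to 3002 without P195A/P195A replicate 3.

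The 11 genes of at least 1 CPM from Adar to Tpm3 (chromosome 3, 89715022 to 90100902, 386 kb) had log2 fold changes above 0 in each P195A genotype, and 1 passed in P195A/+, 9 in P195A/P195A and 3 in P195A/-. This interval was chosen after its values were seen. The lowest was Chrnb2 in P195A/-, at 0.019 (SE 0.128; adjusted p = 0.97). Without Adar, their median log2 fold change was 0.62 in P195A/+ (range 0.36 to 0.73), 0.93 in P195A/P195A (0.71 to 1.01) and 0.56 in P195A/- (0.02 to 0.85). Genes within 3 Mb on either side, 94 in number, had medians of 0.05, 0.02 and 0.06. Of the 10 genes passing in P195A/P195A, 9 lay inside the interval, which was drawn from them. Of the 94 flanking genes 4 had an unadjusted p under 0.05 (4.26%, against 5.89% of all genes). By library the median inside was 0.54 to 0.61 in P195A/+ and 0.42 to 0.60 in P195A/-. In P195A/P195A it was 0.97, 0.53, 1.02 and 0.90, and -0.03 to 0.01 in wild type. Rps27, a ribosomal protein gene beyond Tpm3 with a mean of only 1.83 CPM, was named after its values were seen. It had 1.83 (SE 0.466), 1.83 (SE 0.449) and 1.57 (SE 0.473) and did not pass.

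**Figure D2:**
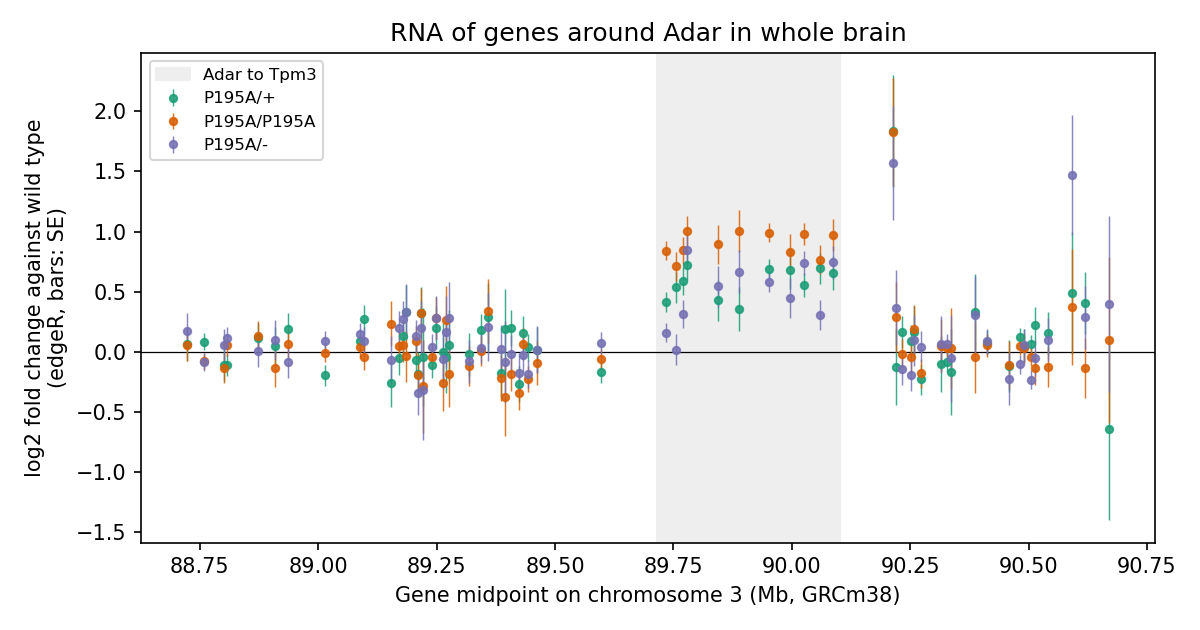
Log2 fold change against wild type (edgeR, bars are SE) of genes by their midpoint on chromosome 3 in Mb, for P195A/+ (green), P195A/P195A (orange) and P195A/- (violet), with the interval from Adar to Tpm3 in grey. Shown are genes of at least 1 CPM, 11 inside the interval and 54 within 1 Mb of it. Inside it the medians without Adar were 0.62, 0.93 and 0.56.

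As sets, 7 lists were lower and 1 higher in P195A/P195A than in wild type, and 0 of 24 passed with an estimated correlation or with fry. Interferon-stimulated genes had a median of -0.15, with 33 of 51 lower (adjusted p = 0.0239; adjusted p = 0.523 with an estimated correlation). By edgeR 0 members passed over all genes, 8 had an unadjusted p under 0.05 (2 higher and 6 lower), and Dhx58, a cytosolic RNA sensor gene, passed adjusted over the list alone, at 1.49. The MHC class I list had a median of -0.21 (adjusted p = 0.037), with H2-D1 at -0.25 and Psmb9 at -1.15, and astrocytes had -0.15 (0.00553), with Glul, the glutamine synthetase gene, at -0.28 and Slc1a2, a glutamate transporter gene, at -0.19. Meninges and fibroblasts had -0.19 (0.0239; Dcn -0.42) and glucocorticoid targets -0.24 (0.00434; Sgk1 -0.52 and Pdk4 -0.67); for these 4 lists adjusted p = 0.523 with an estimated correlation. Blood cells had -1.03 (adjusted p = 0.037; Hbb-bs -1.16) and cholesterol synthesis -0.09 (0.0239; Stard4 -0.29), with adjusted p = 0.615 with an estimated correlation for both. Proliferating and immature neural cells were higher, at 0.16 (0.0301; adjusted p = 0.523 with an estimated correlation), with Dcx, a gene of migrating neuroblasts, at 0.47 and Dlx1 at 0.53; 1 member passed adjusted over the list alone. No member of these lists passed over all genes by edgeR. Olfactory bulb markers were higher in 13 of 15 genes (median 0.49) beside them, the list added after the data were examined.

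These list calls varied with the animals. The count was 2 without P195A/P195A replicate 4, 3 without replicate 2, 4 without replicate 1 and 4 without wild-type replicate 3, 2 without P195A/P195A replicates 2 and 3 together, and 0 among animals of 48 days. There the list antigen presentation by MHC class I, P195A/P195A against wild type, turned to 0.07 (adjusted p = 0.759). The interferon call was lost without wild-type replicate 3 (-0.03), P195A/P195A replicate 2 (-0.15) or replicate 4 (-0.16). MHC class I lost its call without wild-type replicate 1 (-0.14) or 3 (0.01) and without P195A/P195A replicate 1 (-0.16), 2 (-0.14) or 4 (-0.20). Blood cells did so without wild-type replicate 1 (-0.50) or 3 (-0.98) and P195A/P195A replicate 1 (-0.997), 2 (-0.81) or 4 (-1.12). Meninges lost it without P195A/P195A replicate 2 (-0.07) or 4 (-0.19), astrocytes without replicate 2 (-0.11), and glucocorticoid targets without replicate 1 (-0.15). Proliferating and immature cells lost it without wild-type replicate 3 (0.08) or P195A/P195A replicate 1 (0.19), 3 (0.17) or 4 (0.07), and cholesterol synthesis without wild-type replicate 2 (-0.06) or 3 (-0.08) or P195A/P195A replicate 2 (-0.07) or 4 (-0.08).

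P195A/- against wild type addresses the mutation opposite a null allele. Rps3a2 (chromosome 14, 88123017 to 88123808) and Rps3a3 (chromosome 13, 108670603 to 108671397), near-identical copies of the ribosomal protein gene Rps3a1, had 22.2 ± 7.36 and 33.1 ± 5.56 CPM in P195A/- (SD, n = 3), at least 450-fold and 201-fold (counting interval 109 to 419) higher than in wild type (adjusted p = 2.33e-05 and 1.53e-07). Hist1h2al, a histone gene 99.41% identical to Hist2h2aa2, had 156 counts against 1, a ratio of 186 (32.9 to 7380; adjusted p = 0.00873). Because these copies may share reads with their parents, their changes are uncertain. Near Adar, Ube2q1 rose 0.85 (SE 0.132; adjusted p = 0.0269), Ubap2l 0.74 (SE 0.0974; 0.00747) and Atp8b2 0.58 (SE 0.0811; 0.00958), while Adar had 0.16 (0.506). Serpini1, the neuroserpin gene of neurons (chromosome 3, 75557547 to 75643495), fell from 362.6 ± 18.0 to 238.3 ± 12.9 CPM, -0.61 (SE 0.0967; 0.0326). In all, 6 genes rose and 1 fell, with 2112 at an unadjusted p under 0.05, where chance gives 998; DESeq2 passed 200 (32 higher and 168 lower), and gave no adjusted p for Rps3a2, Rps3a3 and Hist1h2al. A fit of only these genotypes and the set without a filter passed 16 each, and limma-voom 5.

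The count in P195A/- was 2 without any one of the wild-type replicates and 3 without P195A/- replicate 2. Without wild-type replicates 1, 2 and 3 in turn Ube2q1 had 0.81, 0.85 and 0.87, Ubap2l 0.73, 0.75 and 0.73, Atp8b2 0.58, 0.53 and 0.61, and Serpini1 -0.65, -0.57 and -0.61, and none of these 4 passed. Without P195A/- replicate 1, 2 and 3 Ube2q1 (0.85, 0.84 and 0.86) and Serpini1 (-0.59, -0.59 and -0.64) did not pass, and Atp8b2 did not without replicate 1 (0.50) or 2 (0.57). Hist1h2al passed in 1 of these 6 fits, that without P195A/- replicate 1 (adjusted p = 0.0478), with an adjusted p of 0.0511 to 0.118 in the others.

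Interferon-stimulated genes were higher in P195A/-, with a median of 0.37 and 45 of 51 higher (adjusted p = 5.67e-08; adjusted p = 0.17 with an estimated correlation; fry 0.0403). By edgeR 0 passed over all genes, 11 had an unadjusted p under 0.05, all higher, and 3 passed adjusted over the list alone: Ifit1, which binds viral RNA, at 1.14, Ifi44 at 1.52 and Ifi27l2a at 2.24. By library the list's median stood at 0.276, 0.604 and 0.332, against -0.091 to 0.094 in wild type. Markers of microglia and MHC class I genes did not pass here, the latter with a median of 0.06. Targets of the integrated stress response, the translational stress programme led by Atf4, were lower, at -0.13 (adjusted p = 0.0206; adjusted p = 0.944 with an estimated correlation), with Asns, the asparagine synthetase gene, at -0.47 and Pck2 at -0.46. Immediate early genes were lower, at -0.26 (4.39e-04; adjusted p = 0.969 with an estimated correlation), with Fosb at -1.01 and Egr3 at -0.36; 1 member passed adjusted over the list alone and none over all genes. These 3 lists became 7 without wild-type replicate 2 and 5 without P195A/- replicate 2 or 3. The stress response call was lost without wild-type replicate 1 (-0.10) or P195A/- replicate 3 (-0.10). Olfactory bulb markers were lower in 12 of 15 genes (median -0.48), and mitochondrial genes took 1.57% of the counts of replicate 3.

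**Figure D3:**
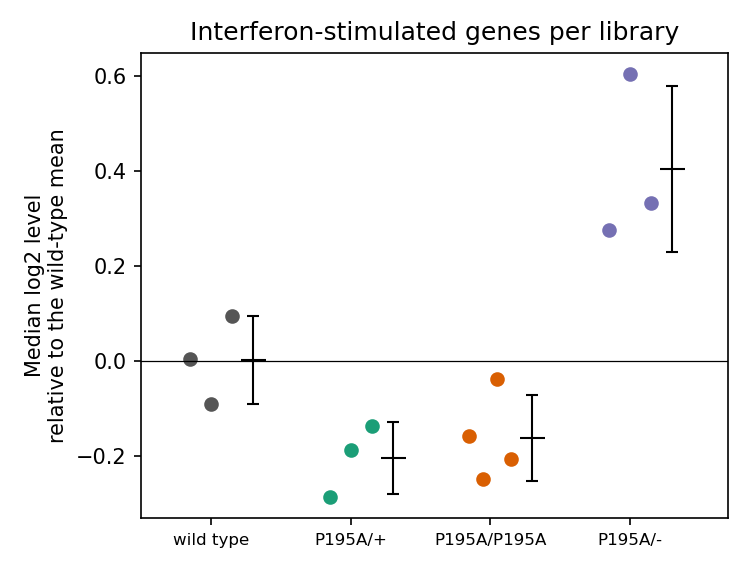
Median log2 level of 51 interferon-stimulated genes in each library relative to the wild-type mean (points), with the mean and SD of each genotype in black. The P195A/- libraries sit at 0.276 to 0.604, and the other 10 libraries at -0.286 to 0.094.

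The direct comparison of P195A/- with P195A/P195A asks what loss of the other allele adds. Adar fell by 0.68 on the log2 scale by edgeR (SE 0.0772, adjusted p = 7.73e-04). It passed in 17 of 18 alternatives, over which its adjusted p reached 0.303. Rps3a2 (at least 512-fold), Rps3a3 (175-fold, counting interval 102 to 330), Gm3608 (82.6-fold, 54.4 to 132) and Hist1h2al (at least 70.3-fold) were higher, with the limit on shared reads. Floors of 3 counts over the group stand behind these lower bounds. Capza1, the actin-capping protein gene (chromosome 3, 104822779 to 104864505), may share reads with Gm3608. It fell from 76.2 ± 4.80 (SD, n = 4) to 51.0 ± 2.17 CPM (n = 3), -0.58 by edgeR (SE 0.0877, adjusted p = 0.0204). Cdhr1 (chromosome 14, 37077857 to 37098347), a cadherin gene of olfactory bulb projection neurons, fell from 22.3 ± 2.39 to 5.91 ± 3.64 CPM, -1.92 (SE 0.29; 0.0253), and S100a5, of olfactory sensory neurons, fell from 0.946 CPM to 0 (adjusted p = 0.0266). S100a5 and Hist1h2al averaged under 1 CPM and were named after their values were seen. Olfactory bulb markers, of which these are 2, were lower in 15 of 15 genes (median -0.64). In all 4 genes rose and 4 fell, with 1361 at an unadjusted p under 0.05; DESeq2 passed 52, the set without a filter 29, limma-voom 8, a fit of only these genotypes 5 and animals of 42 days alone 5. The count was 5 without P195A/P195A replicate 1 or 4, and 15 without replicate 2. S100a5 passed in 1 of the 7 fits that left out a library, that without P195A/P195A replicate 2 (adjusted p = 0.0396), and Hist1h2al in all 7. Cdhr1 did not pass without P195A/P195A replicate 1 (-1.99), 3 (-1.86) or 4 (-1.91) or P195A/- replicate 2 (-1.65) or 3 (-1.72), and Capza1 without P195A/P195A replicate 1 (-0.57) or 4 (-0.55) or P195A/- replicate 1 (-0.55), 2 (-0.61) or 3 (-0.57).

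Interferon-stimulated genes were higher in P195A/- than in P195A/P195A, with a median of 0.49 and 46 of 51 higher (adjusted p = 9.93e-19), and this call held with an estimated correlation (adjusted p = 0.0113 with an estimated correlation) and with fry (0.00238). Over all genes 0 passed by edgeR, 20 had an unadjusted p under 0.05, all higher, and 13 passed adjusted over the list alone: Lgals9, Rsad2, Irf7, Ifi44, Gbp2, Oasl2, Usp18, Trim30a, Lgals3bp, Ifit1, Bst2, Ifit3 and Ifi27l2a. Ifit1 had 1.42, Ifi44 1.93 and Ifit3 1.28, and DESeq2 passed these 3 over all genes (0.00195, 0.00771 and 0.0147). Ifit3 also passed without P195A/P195A replicate 3 (1.61, adjusted p = 0.0389). MHC class I genes were higher by camera, at 0.22 (adjusted p = 0.00432, B2m 0.73 and H2-K1 0.53). So were oligodendrocytes at 0.17 (4.89e-04, Mbp 0.33 and Mobp 0.35) and their precursors at 0.08 (0.0136, Sox10 0.51). For these 3 lists adjusted p = 0.46 with an estimated correlation. B2m stood at 26.04 CPM in P195A/- replicate 3 and at 14 and 13.37 in the others, against 6.714 to 13.33 in P195A/P195A. H2-K1 overlapped, at 15.77 to 24.15 CPM in P195A/- and 11.68 to 17.58 in P195A/P195A. Meninges and fibroblasts were higher, at 0.19 (0.0331; adjusted p = 0.66 with an estimated correlation; the collagen gene Col3a1 1.28), and immediate early genes lower, at -0.19 (0.00432; adjusted p = 0.837 with an estimated correlation; Fosb -0.86). Adjusted over the list alone 3 oligodendrocyte, 2 precursor, 1 meningeal and 1 immediate early gene passed, the last being Fosb. It also passed over all genes by edgeR without P195A/P195A replicate 2 (-1.01). DESeq2 passed Fosb (-0.87, adjusted p = 0.00771) and Col3a1 (1.28, adjusted p = 0.0258) over all genes as well. In all 5 lists were higher and 1 lower, and 1 passed with an estimated correlation and with fry.

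Leaving out P195A/- replicate 2 left 1 list in this comparison, with MHC class I at 0.13, oligodendrocytes at 0.17, precursors at 0.05, meninges at 0.18 and immediate early genes at -0.17. There were 3 lists without P195A/P195A replicate 2, with MHC class I at 0.17, precursors at 0.06 and meninges at 0.17 no longer called. Meninges lost the call without P195A/P195A replicate 4 (0.18) or P195A/- replicate 1 (0.07), and immediate early genes without P195A/P195A replicate 3 (-0.10) or 4 (-0.19). Among animals of 42 days the direction of immediate early genes, P195A/- against P195A/P195A, turned, to 0.0408 (adjusted p = 0.542). Across the 4 comparisons 11 of the 24 lists never passed. Among these, neurons had medians of -0.10 to 0.01, microglia and macrophages -0.02 to 0.02, the unfolded protein response 0.00 to 0.09, inflammation and cell death -0.05 to 0.09, double-stranded RNA editing and sensing -0.02 to 0.15, lymphocytes and neutrophils -0.16 to 0.12, choroid plexus and ependyma -0.09 to 0.16, pituitary and pineal -0.82 to 0.04, circadian clock output -0.07 to 0.03, sex-linked controls -0.12 to 0.06 and genes with known recoding sites -0.01 to 0.03. Median, mean and test differed in sign for some of these, such as the pituitary and pineal list in P195A/- against wild type, with a median of -0.79, a mean of -1.002 and a test direction upward.

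Editing levels, the percent of A plus G reads that carried G at a site with a reference A, rose at single sites in P195A/P195A. A 3' UTR site of Gnl3l (chromosome X, 150984618) was edited at 71.1% ± 3.85 (SD, n = 4) against 55.2% ± 3.15 in wild type (n = 3), a log2 odds ratio of 1.00 (SE 0.165; adjusted p = 4.63e-06) on 447 to 651 reads per library. A site of Cds2 (chromosome 2, 132309633), a phospholipid synthesis gene, rose to 11.3% ± 1.51 from 5.02% ± 1.34 (1.26, SE 0.209; 4.63e-06), and one of Kif3c (chromosome 12, 3404616), a kinesin motor gene, to 18.5% ± 4.65 from 6.69% ± 0.586 (1.69, SE 0.311; 1.28e-04). The 2 others with the smallest p lay in a ribosomal RNA repeat on chromosome 17, at 39844592 (26.4% ± 3.33 against 14.6% ± 7.41; 3.91e-06) and at 39845506 in Gm26917 (6.09% ± 0.437 against 3.51% ± 0.970; 3.91e-06). Reads of such repeats come from many copies and depth was capped at 3000 per the file headers, so their levels are uncertain. Of 11551 tested sites, 32 rose and 0 fell by edgeR, and 921 had an unadjusted p under 0.05 (680 higher, 241 lower), where chance gives 578. Of the 32, 19 lay in 3' UTRs and 2 in coding sequence (Chtf8 and Grik2, named after their values were seen), and at 28 the 2 genotypes did not overlap, which passing the test favours. Over all tested sites the share without overlap was 8.28%, where chance gives 5.71%. limma passed 0 sites and Fisher's exact test on pooled reads 122. The count was 14 without P195A/P195A replicate 1, 10 without replicate 3 and 20 without replicate 4, and 9, 11 and 15 without wild-type replicates 1, 2 and 3. It was 19 at 5 or more reads per library, 7 among animals of 48 days and 14 without P195A/P195A replicates 2 and 3 together.

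In P195A/- against P195A/P195A, the sites that passed were all less edited. Gnl3l X 150984618 fell from 71.1% ± 3.85 (SD, n = 4) to 51.1% ± 0.557 (n = 3), a log2 odds ratio of -1.24 (SE 0.171; adjusted p = 1.88e-09), a 3' UTR site of Bri3bp (chromosome 5, 125456605) from 85.7% ± 3.13 to 62.6% ± 6.81 (-1.89, SE 0.328; 2.16e-05), and Cds2 2 132309880 from 90.5% ± 0.895 to 83.0% ± 2.52 (-0.96, SE 0.193; 0.00146). In the ribosomal repeat, Gm26917 fell at 39843752 from 3.22% ± 0.986 to 1.16% ± 0.0839 (3.28e-16) and at 39845506 from 6.09% ± 0.437 to 3.67% ± 0.583 (1.01e-05), uncertain as above. Such p values draw on read depth and on a spread partly shared over sites. They can be far smaller than the spread between the animals would give. Of 11818 tested sites 14 fell and 0 rose, 9 of them in 3' UTRs, with 864 at an unadjusted p under 0.05 against 591 by chance, and at 14 of 14 the genotypes did not overlap, which passing favours (7.37% of all tested sites, 5.71% by chance). Counts were 26 at 20 or more reads, 35 at 50 or more, 0 by limma, 85 by Fisher's exact test on pooled reads and 3 among animals of 42 days. Without P195A/- replicates 1, 2 and 3 they were 8, 9 and 4, and without P195A/P195A replicate 3, 8. Without P195A/- replicate 3 the sites of Bri3bp (-1.60) and Cds2 (-0.87) did not pass.

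Against wild type, 1 of 14019 sites passed in P195A/+ and 1 of 14177 in P195A/-, in both the repeat site at 39844592, at 25.2% ± 7.56 and 26.4% ± 4.49 (SD, n = 3 each) against 14.6% ± 7.41 (n = 3; adjusted p = 0.0298 and 0.00234); the genotypes overlapped there. Unadjusted p under 0.05 were 847 (701 by chance) and 570 (709 by chance). Of these, 664 were higher and 183 lower in P195A/+, and 349 higher and 221 lower in P195A/-. Over all tested sites 59.6% were higher in P195A/+, 57.3% in P195A/P195A and 53.4% in P195A/-. limma passed 0 sites in both, and Fisher's exact test on pooled reads 25 and 2. Outside ribosomal repeats the count was 0 in both by edgeR, and 0 in P195A/+ with sex as a covariate or with levels of 5 to 95%. The site in P195A/+ failed without P195A/+ replicate 2 (0.69) or 3 (0.99) or wild-type replicate 2 (0.73) or 3 (0.815), with a count of 0, and 2 sites passed without wild-type replicate 1. In P195A/- it failed without P195A/- replicate 2 (0.95) or 3 (1.03) or wild-type replicate 2 (0.82) or 3 (0.89), with a count of 0.

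In 10 genes with known recoding sites, the coding site with the most reads, which need not be the recoding site itself, did not pass in any comparison by edgeR. Another such gene, Grik2, held 1 of the 2 passing coding sites of P195A/P195A named above, at 6.54% ± 3.60 (SD, n = 4) against 0.878% ± 0.902 (n = 3; adjusted p = 0.0371). Outside coding sequence, an intron site of Gria4 passed by edgeR in P195A/P195A, at 49.1% ± 16.3 against 14.0% ± 3.02 in wild type (adjusted p = 0.00645). A noncoding exon site of Gm22413 and Gria3 passed in P195A/-, at 41.4% ± 4.53 against 67.8% ± 8.38 in P195A/P195A (0.0425). Both were named after their values were seen. At the sites with the most reads, the levels in wild type and P195A/P195A were 17.8% ± 1.75 and 20.3% ± 2.02 for Cadps, 40.3% ± 5.56 and 37.4% ± 2.39 for Kcna1, 58.0% ± 6.57 and 55.6% ± 3.05 for Unc80, 43.3% ± 4.44 and 39.9% ± 3.85 for Son and 95.5% ± 2.21 and 95.2% ± 1.21 for Gabra3 (SD, n = 3 and 4). Cyfip2, Gria2, Azin1, Copa and Gria3 had 1.23 to 4.45% in wild type. The smallest unadjusted edgeR p was 0.0259, for Copa in P195A/- (7.45% ± 2.01) against P195A/P195A (4.44% ± 2.17), with an adjusted p of 0.644.

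Mean editing differed over the 4 genotypes on the 9791 sites read in all 13 libraries (permutation F test, p = 0.00427 over 1201200 arrangements), at 15.5% ± 0.63 in wild type (SD, n = 3), 17.3% ± 0.37 in P195A/+ (n = 3), 16.8% ± 0.24 in P195A/P195A (n = 4) and 16.0% ± 0.50 in P195A/- (n = 3). Within each comparison the differences were 1.83 points for P195A/+ and 1.27 for P195A/P195A against wild type (exact permutation p = 0.1 and 0.0571, the smallest these sizes allow), 0.684 for P195A/- (0.3) and -0.633 for P195A/- against P195A/P195A (0.171). Leaving out 1 library at a time gave 1.503 to 2.19, 0.919 to 1.63, 0.354 to 1.05 and -0.877 to -0.364 points in that order. The 1858 joint sites in 3' UTRs had 13.9% ± 0.40, 15.1% ± 0.20, 15.4% ± 0.57 and 13.8% ± 0.24 in the same order. The P195A/- difference from P195A/P195A was -0.223 points at 5 or more reads (exact permutation p = 0.514), and -1.30 at 20 or more and -1.38 at 50 or more (0.0571 each). That of P195A/- from wild type was 0.15 at 20 or more reads, 0.114 at 50 or more, 0.406 with reads pooled over sites and 0.01 in 3' UTRs. Across the 13 animals, Adar CPM and mean editing had Pearson's r = 0.607 (permutation p = 0.0284) and Spearman's rho = 0.72 (permutation p = 0.00697), r = 0.593 without the 2 animals farthest from the median of Adar, and r = 0.404 within genotypes (exact permutation within genotypes over 5184 orders, p = 0.102). The former p values permute across genotypes, which differ in both quantities. It was the 1 relation of this kind computed, so no adjustment applied.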

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

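Of the tests in this part, the splits of the libraries and the test of age were chosen before their results were seen, and the tests of the interval around Adar, of shared reads, of swapped libraries, of microglia and of lower editing only after.

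Of 78 values examined in the 4 P195A/P195A libraries, 4 had a sample far from the others, where chance alone gives about 1 in 20 groups, 3.9 here. H2-K1 stood at 17.58 CPM in replicate 3, with the others at 11.68 to 12.52. Mobp stood at 605.8 CPM in replicate 2, with the others at 670.3 to 677.6. Tcf7l2 stood at 24.66 CPM in replicate 2, with the others at 30.4 to 31.44. Mean editing of 3' UTR sites stood at 14.592% in replicate 2, with the others at 15.614 to 15.797%.

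The first pattern is the higher RNA of Adar and its neighbours, by their median in each P195A genotype. The interval was drawn from the genes that moved, so only genes outside it were tested for a wider cause. In P195A/+ against wild type 4.44% of the genes outside had an unadjusted p under 0.05 by edgeR, where chance gives 5%. A fit of only these 2 genotypes gave 1295 of 19092 genes in all, so the share depended on the fit. In P195A/P195A and P195A/- the shares were 5.84% and 10.5%. In P195A/P195A, leaving out 1 library gave from 726 genes (without wild-type replicate 3) to 3002 of 19891 (without P195A/P195A replicate 3). A response spread over the genome therefore cannot be told apart in any P195A genotype. A strain haplotype around Adar cannot be told apart either. Of the flanking genes 5.32%, 4.26% and 10.6% had an unadjusted p under 0.05 in P195A/+, P195A/P195A and P195A/-, against 4.48%, 5.89% and 10.6% of all genes. The 95% intervals of the flanking shares were 1.75 to 12, 1.17 to 10.5 and 5.22 to 18.7%. Serpini1 and Capza1, which passed in comparisons of P195A/-, also lie on chromosome 3, beyond these flanks. The parents of the near-identical copies lie there as well. Cdhr1, which passed too, lies on another chromosome. These genes were picked for passing and cannot decide. A candidate explanation is an extra copy of the interval on the P195A allele, which stays open. Medians of 0.62, 0.93 and 0.56 lay within 0.07 of the log2 doses 0.58, 1 and 0.58. However, 5 of 30 gene values lay more than 2 SE from the dose. About 1.4 would follow from chance for independent values. The 30 are the same 10 genes in each P195A genotype against the same wild-type libraries, so the count cannot decide. Of the 5 values, Chrnb2, which overlaps the end of Adar, stood at -4.41 SE from the dose in P195A/- (0.019) and -2.38 SE in P195A/P195A (0.711). In P195A/- 4632404H12Rik (0.312) and 4933434E20Rik (0.306) lay below it and Ube2q1 (0.849) above. P195A/P195A replicate 2 had an interval median of 0.53, near the dose of a single such allele, but its genes did not move alike. Its Atp8b2 stood at 224.6 CPM, with the other P195A/P195A libraries at 224.9 to 241.7 and P195A/+ at 182.7 to 195.1. Adar (282.4 CPM), Ubap2l (183.4) and Il6ra (11.6) also lay above all P195A/+ libraries. Ube2q1 (83.63), Tpm3 (78.37), Chrnb2 (104.1) and 4933434E20Rik (72.97) lay below all of them, and 4632404H12Rik (36.41) among them. The cause was not tested. As Adar itself is in the interval, the effect of the mutation and of the dose of Adar cannot be separated in these animals.

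The second pattern is the genes present in some genotypes and near 0 in others, each a near-identical copy of a gene on chromosome 3. A mislabelled or swapped library cannot be told apart: Xist and Ddx3y differed from the sex given in 0 libraries, which leaves swaps of animals of the same sex open, and the genes themselves were picked for being on in whole genotypes. Reads shared with the parent gene may account for Gm3608 and, in part, the Rps3a copies: the sum of copy and parent changed by at most 0.29 on the log2 scale, where 0.43 to 0.68 would follow if the parent had kept its level; the bound of 0.3 was set after the values were seen. The Rps3a sum still rose by 0.27 to 0.29, and Hist1h2al was too low beside its parent to decide. Sequence variants on chromosome 3 that travel with the alleles were not tested.

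The third pattern is the higher interferon-stimulated genes in P195A/-. Age is argued against for the comparison with P195A/P195A, since among animals of 42 days the median was 0.543, while wild-type animals shared no age with P195A/-. A larger share of microglia is argued against as well, since the upper quartile of the microglia list was 0.223 against P195A/P195A and 0.199 against wild type, under the medians of 0.492 and 0.374 of the interferon list. Lower editing of the sites read here cannot be told apart: mean editing in P195A/- was 0.684 points above wild type, with overlapping libraries (0.15 at 20 or more reads, 0.114 at 50 or more and 0.01 in 3' UTRs), but against P195A/P195A it was -0.633 (-1.295 at 20 or more reads, -1.378 at 50 or more and -1.54 in 3' UTRs), with 14 sites lower and 0 higher, and sites read here need not be those that matter. What stays open, as a hypothesis, is an effect of the genotype. Adar itself was lower than in P195A/P195A (-0.68) but not lower than in wild type (0.16), and its dose was not tested as a cause.

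Over the 35 splits of the 7 libraries, the real split gave the most genes and sites in 2 comparisons, with 1 of 35 as large each time. In P195A/P195A against wild type these were 10 genes (highest other 7) and 32 sites (highest other 13). In P195A/- against P195A/P195A they were 8 genes (highest other 2) and 14 sites (highest other 6). A share of 1 in 35 is the smallest these sizes allow, and it was not adjusted over the counts examined. The 2 comparisons share the P195A/P195A libraries, and the splits exchange animals of different age, so chance is not excluded for these 4 counts. The split with 7 genes put P195A/P195A replicate 2 with the 3 wild-type libraries. The numbers of lists cannot be set apart from chance, with 6 of 35 splits giving as many as 8 (highest other 11) and 16 of 35 as many as 6 (11). For the comparisons of 3 against 3, the 10 splits are too few for a share under 0.05: the real and highest other values were 2 and 1 genes, 6 and 8 lists (3 splits as large) and 1 and 1 sites (3) in P195A/+, and 7 and 1 genes, 3 and 7 lists (7) and 1 and 1 sites (2) in P195A/-.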

How the results depend on the processing

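Fits of all 13 libraries for sites, sites outside ribosomal repeats, sites read in all 13 libraries, omission of the P195A/P195A libraries at the ends of the first principal component (replicates 2 and 3) and weaning weight at 1 age were chosen after seeing the data; the other alternatives were not. In the order P195A/+, P195A/P195A and P195A/- against wild type, then P195A/- against P195A/P195A, the numbers of genes were 2, 10, 7 and 8. DESeq2 gave 19, 19, 200 and 52, only the 2 genotypes 11, 5, 16 and 5, and no filter on low counts 7 in P195A/+ and 16 in P195A/- against wild type, and 29 in P195A/- against P195A/P195A. Animals of 1 age gave 5 (48 days, P195A/P195A against wild type) and 5 (42 days, P195A/- against P195A/P195A); no age was shared in the other comparisons, so no value was made. Smaller groups mean fewer samples; otherwise the cause was not tested.

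Numbers of sites were 1, 32, 1 and 14. limma on log2 ratios gave 0 in all 4, and Fisher's exact test on pooled reads, which ignores the spread between animals, 25, 122, 2 and 85. At least 5 reads gave 19 for P195A/P195A against wild type; 20 reads gave 2 in P195A/+ and 26 in P195A/- against P195A/P195A; 50 reads gave 0 in P195A/- against wild type and 35 in P195A/- against P195A/P195A. Levels of 5 to 95% and sex as a covariate gave 0 in P195A/+, all 13 libraries in 1 fit 4, and sites outside ribosomal repeats 0 in P195A/+ and 0 in P195A/- against wild type. Animals of 48 days gave 7, those of 42 days 3, and omission of the libraries at the ends of the first component 14 for P195A/P195A. A fit of only the 2 genotypes is the same as the reported one for sites. The cause of these moves was not tested.

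Numbers of lists were 6, 8, 3 and 6. With an estimated correlation they were 0, 0, 0 and 1, and with fry 0, 0, 1 and 1. Animals of 48 days gave 0 and omission of the end libraries 2 in P195A/P195A. The interferon-stimulated list lost its call in P195A/+ (-0.21) and P195A/P195A (-0.15) with an estimated correlation or fry, and in P195A/- against wild type (0.37) with an estimated correlation; these tests do not enter the median. The median of interferon-stimulated genes, P195A/P195A against wild type, was -0.0925 at 48 days and -0.15 without the end libraries (adjusted p = 0.068; adjusted p over its alternatives reached 0.544). The list antigen presentation by MHC class I, P195A/P195A against wild type, reversed among animals of 48 days, to 0.07 (adjusted p = 0.759), and immediate early genes, P195A/- against P195A/P195A, reversed among those of 42 days, to 0.0408 (0.542); the cause was not tested.

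With the replicate block, replicate numbers served as a block, although residuals of equal numbers correlated at only -0.0744 to 0.124 over the comparisons, so the numbers do not pair animals; genes were 2, 8, 6 and 7, sites 0, 16, 1 and 10, and lists 6, 4, 5 and 5.

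Mean editing moved to 1.22 points in P195A/+ at 50 reads, and to -0.223 at 5 reads, -1.295 at 20, -1.378 at 50 and -1.0 with reads pooled over sites in P195A/- against P195A/P195A. In P195A/- against wild type it went from 0.684 to 0.15 at 20 reads, 0.114 at 50 and 0.406 with pooled reads, within 1 SD of libraries. Leaving out 1 library at a time gave 1 to 2, 5 to 13, 2 to 6 and 5 to 15 genes, 0 to 2, 9 to 27, 0 to 1 and 4 to 17 sites, and 3 to 7, 2 to 11, 2 to 7 and 1 to 7 lists. The interferon list ranged from -0.24 to -0.15, -0.19 to -0.0311, 0.31 to 0.50 and 0.37 to 0.55, mean editing from 1.503 to 2.19, 0.919 to 1.63, 0.354 to 1.05 and -0.877 to -0.364 points, and weaning weight from -2.36 to -1.93 g; among mice of 48 days weaned at 19 days it was -2.1 g (exact permutation p = 0.333), with 2 mice per group. Of 794 named-gene values without 1 library 741 kept direction and call, 51 lost the call and 2 gained it; of 1221 in other settings 1168, 32 and 21. For named sites 332 of 342 and 527 of 552 kept both and the rest lost the call, and for lists 103 of 152 and 122 of 189, with 49 and 65 losing it and 2 reversing. Named values that passed in neither setting but changed sign are counted as kept. Depth limits the sites, at a median of 22 to 25 reads per library.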

Other observations

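Tests in this part were chosen after the data were examined, except the deposited scores, which are given as values.

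No fixed list covered the olfactory bulb, and the list added for it includes Cdhr1 and S100a5, which had passed before it was written, so no test of it is given. Relative to wild type, the list median by library was -0.453, -0.732 and -0.244 in P195A/+, 0.262, 0.461, 0.644 and 0.427 in P195A/P195A, and -0.326, -0.721 and -0.499 in P195A/-. Whether the share of the bulb kept at dissection differed was not tested.

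The highest deposited JACUSA2 score of each comparison was 15.8 for Gnl3l X 150984618 in P195A/+, 22.01 for 17 39843752 in P195A/P195A, 11.4 for the same site in P195A/- against wild type and 23.3 for Gnl3l X 150984618 in P195A/- against P195A/P195A. Over sites, which are not independent replicates, the score and the edgeR p ranked sites with a correlation of 0.965 to 0.973 on the log scale.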
